A study of Mus musculus with 7 samples.

How the data were processed

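Retinal endothelial cells of mouse pups at postnatal day 6 were profiled by CEL-Seq2, a plate-based method that tags the 3′ end of each transcript with a unique molecular identifier (UMI), so that each original molecule is counted. Per the labels' protocols, the deleted mice carried 2 floxed copies of Hbo1 (Kat7) and the control mice 1, all with the tamoxifen-induced endothelial recombinase Cdh5-creERT2 and the mTmG reporter, which turns on EGFP after recombination. Tamoxifen (50 µg) was injected into the stomach on postnatal days 1 and 2, and PECAM1+ EGFP+ cells were sorted into wells that held ERCC spike-in RNA.

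The authors deposited counts of UMIs per gene and well, without normalization, for 34262 genes, and a table of counts for 89 ERCC spike-ins. The deposited values were checked to be whole numbers, and the deposited reads mapped to exons and introns came to 17.5 per UMI. The genome build was GRCm38.p6 per the submitters' processing notes, and the aligner and counter are not given in the sources used here. A deposited sheet of wells gave the plate, genotype, mouse, sex and sequencing run of each well, read counts per mapping class, and the intensity of each sort channel per the file headers. Of the gene identifiers, 34236 matched GENCODE release 21 of the mouse, which gave names and GRCm38 coordinates, and 26 did not. Every column of wells was matched to a plate.

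The sheet held 2336 wells of 1 cell and 34 wells of 20 cells on 7 plates. A cell was kept with at least 1000 UMIs, at least 500 genes, at most 20% mitochondrially encoded UMIs and at most 50% ERCC UMIs, which left 2240 cells. No doublet caller was run, since 1 cell was sorted per well. The sheet names 12 mice, 6 control and 6 deleted, where the series design text states 4 and 4, and all 12 were used. Mice are named by genotype and a number given in order of their plates. Per the sheet control 1, control 5, deleted 2 and deleted 5 were female and the rest male, so that the sexes differ within plate sets LC294, LC392 and LC396. The control mice 1 to 6 gave 319, 183, 179, 147, 184 and 163 kept cells with 3255670, 2335539, 2136023, 2707052, 2256587 and 2093049 UMIs. The deleted mice 1 to 6 gave 183, 183, 147, 184, 184 and 184 kept cells with 2464338, 2156053, 2478201, 2565375, 2589097 and 1820041 UMIs. Levels are given as counts per all UMIs of the mouse, scaled to CPM. Depth sets the precision of low genes: Kat7 rested on 7 to 56 UMIs per mouse, and intervals on single counts cover counting error only.

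UMIs of the kept cells were summed per mouse, and the genotypes were compared with edgeR 4.0.16 (quasi-likelihood test, TMM size factors, filterByExpr by genotype, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. The design, the gene lists, the cell filter, the cluster settings and the rule for named genes were fixed before the data were examined. The planned comparison had genotype as its single term. The plate set as a block was listed beforehand as another fit to try. Each plate held cells of 1 control and 1 deleted mouse, except plate LC279 (control 1 alone, another sequencing run) and plates LC396 and LC398, which share control 6 and form 1 set. Mice of a plate set deviated together from their genotype means, with correlations of 0.221 to 0.653 (median 0.540, 6 pairs) against −0.443 to 0.494 (median −0.262) for 30 pairs from different sets, and the pairing comes from the sheet. Deviations from a genotype mean sum to 0, so positive correlations within sets push those of the other pairs down. The median of −0.262 is in part a result of this. The highest of the 30 were pairs across plates LC294 and LC358 (0.494 and 0.473), above 2 of the 6 pairs of a set, and deleted 6 correlated more with control 2 (0.263) than with its own control (0.221). Blocked values are therefore given beside the planned ones. Describing the blocked genes as a result of their own, leaving out plates LC294 and LC358 (8 mice), leaving out the clusters led by intestinal genes, the wells of 20 cells, sex as a covariate and the permutations within plate sets were chosen after seeing the data.

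The named genes are Kat7 and, per comparison, the 10 genes with the largest change in each direction among those that passed with a mean of at least 10 CPM. Where fewer than 10 passed, those of smallest p filled the places and are given as values that did not pass. The 2 to 4 members of smallest p were taken from each list. Genes chosen after their values were seen are said to be so. Results for some genes are not reported here.

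The 32 fixed lists cover 12 cell types (tip, arterial, capillary, venous, proliferating and pan-endothelial cells, mural, myeloid, photoreceptor, glia, neuron and blood) and 20 pathways or complexes. Lists with at least 3 tested genes, 26 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. The cell cycle lists (S phase, G2/M phase, replication licensing) and the proliferating list overlap in kind, and Cxcr4, Dll4, Slc16a1 and Spock2 each stand in more than 1 list. A further 4 lists (enterocyte, goblet, tuft and general epithelium) were written after intestinal genes had been seen to lead some clusters.

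Per-mouse values were compared with two-sided exact permutation tests over mice (924 arrangements, smallest p 0.00216), and within plate sets over 48 arrangements (smallest p 0.0208), in scipy 1.17.1 and numpy 2.4.6. For every difference given within plate sets, values were centred on the mean of their set, without control 1. The difference is the mean of the deleted mice minus that of the controls. It is not the mean difference from the own control, since deleted 5 and deleted 6 share control 6. Cells were clustered with leidenalg 0.10.2 (resolution 0.8, 15 neighbours, 20 principal components, 2000 variable genes, log values centred within plate). A cluster was named only if at least 3 detected markers of the fixed lists defined it, with a threshold on their share set after seeing the data. Classes were compared in mice with at least 10 cells of the class.

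The test was checked on simulated counts drawn from the real means and library sizes, with 100 genes changed by a log2 size of 1 and 100 by 2. The changed genes had a mean of at least 10 CPM. Counts were drawn independently for each gene, and for genotype alone the means held no plate sets. The shared deviation of mice of a plate set is therefore absent there, and those counts of recovered and false calls do not describe the real mice. With genotype alone in 12 mice (12071 genes) it recovered 61 and 92 of them with 10 false calls. With the plate set block in 12 mice (12069 genes) it recovered 84 and 97 with 10 false calls, and with the block in 8 mice (12055 genes) 71 and 99 with 10 false calls. DESeq2 1.42.0, other size factors, other filters on genes and cells, thinning to 1000 UMIs per cell, limma on mean log values, and leaving out mice and plates were run as alternatives. Python 3.11.15, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were also used.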

Results

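Single endothelial cells were isolated from the retinas of 12 mice at postnatal day 6, when blood vessels still spread over the retina. In 6 mice both copies of Hbo1 (Kat7), which encodes a histone acetyltransferase, had been deleted in endothelial cells by tamoxifen, and 6 heterozygous mice with the same recombinase served as controls. The series title places the gene in the sprouting of tip cells, the leading cells of a growing vessel, and the comparison asks which transcripts and cell classes differ when it is lost. The kept 2240 cells gave 1820041 to 3255670 UMIs per mouse, and the median cell of a mouse held 6136 to 18535 UMIs. On the 3 plates that held both sexes, Xist and Y-linked UMIs in wells of the other sex stood at 0.0987 to 0.399 times their level in wells of their own sex.

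Kat7 (ENSMUSG00000038909.16, a protein-coding gene on the minus strand of chromosome 11 at 95274259 to 95310246, GRCm38) was lower in the deleted mice. Its level was 18.4 ± 6.71 CPM in the controls and 5.85 ± 2.31 CPM in the deleted mice (SD, n = 6 each, two-sided exact permutation p = 0.00649). The control mice 1 to 6 had 7.68, 14.6, 23.4, 18.8, 19.1 and 26.8 CPM from 25, 34, 50, 51, 43 and 56 UMIs. The deleted mice 1 to 6 had 6.09, 4.64, 9.28, 7.80, 3.48 and 3.85 CPM from 15, 10, 23, 20, 9 and 7 UMIs. Within plate sets 0 of 6 deleted mice lay above their own control, and the difference of the centred means was −14.5 CPM (exact permutation p = 0.0208, the smallest those arrangements give). In the edgeR fit across genes the log2 fold change was −1.64 (SE 0.34, adjusted p = 0.167), and with the plate set block −1.80 (SE 0.28, adjusted p = 0.00237). DESeq2 gave −1.65 (adjusted p = 0.0120). The deleted exons are not given in the sources used here, and a 3′ tag outside the deleted part would check nothing about the deletion.

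**Figure D1:**
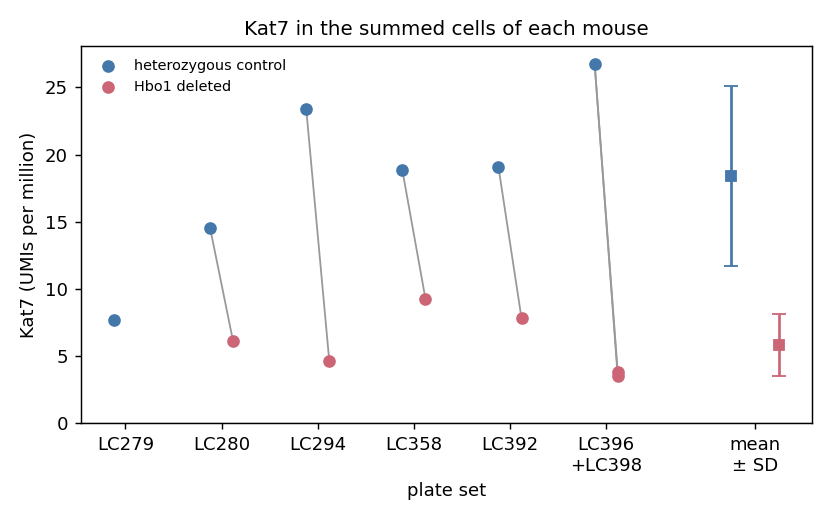
Each point is the Kat7 level of 1 mouse in CPM, controls in blue and deleted mice in red, by plate set, with lines joining the mice of a set and squares giving the mean ± SD of 6 mice. Each of the 6 deleted mice lies below the control of its set, and the means are 18.4 and 5.85.

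In the planned comparison Tgfbi, a secreted matrix protein induced by TGF-beta, fell in the deleted mice, and it was the single gene of 12307 to pass. Its log2 fold change was −1.16 (SE 0.16, edgeR adjusted p = 0.0185), from 71.88 ± 14.96 CPM in 6 control mice to 32.6 ± 7.45 CPM in 6 deleted mice. For Tgfbi, on chromosome 13 at 56609523 to 56639562 (GRCm38), 0 of 6 deleted mice lay above their own control. The next genes by p did not pass. Tceal9 had the smallest p of those with higher values (log2 fold change 0.83, 193 ± 52.3 CPM in controls and 346 ± 66.6 CPM in deleted mice). Tspo of the outer mitochondrial membrane (0.68), the actin-binding Marcksl1 (0.59), the fucosyltransferase Fut4 (1.10), Ap3s1, Ptpre, Nxpe2, Tln2, Fam198b and Prr18 came next, with adjusted p from 0.104 to 0.198 over these genes. Among those with lower values were the endocytic receptor Ly75 (−1.56), the lectin Cd302 (−1.62), the amino acid transporter Slc1a4 (−0.97), the organic anion transporter Slc22a8 (−1.23), Il11ra1, Gltp and Churc1, with adjusted p from 0.104 to 0.167. Ly75 and Cd302 lie close together on the minus strand of chromosome 2 (60292103 to 60383303 and 60251993 to 60284488), and whether their changes are separate was not tested. At an unadjusted p under 0.05 there were 541 genes, DESeq2 called 39 (11 higher, 28 lower), and limma on mean log values called 1. The count was 0 without control 2, control 5, control 6, deleted 1, deleted 5 or deleted 6, 2 without deleted 3 or deleted 4, 3 without deleted 2 and 4 without control 4.

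When the plate set was a block, 168 genes passed, 58 higher and 110 lower in the deleted mice. Control 1, alone in its set, does not inform the genotype difference in this fit, and without control 1 166 passed. All 168 had the same direction in the fit without the block. The genes that rose most included Esm1, a proteoglycan secreted by tip cells (log2 fold change 1.59, SE 0.24, adjusted p = 0.00220), and Cxcr4, the receptor of the chemokine CXCL12 (1.16, SE 0.15, adjusted p = 5.71e-04). Esm1 stood at 23.8 ± 19.5 CPM in controls and 47.6 ± 28.4 CPM in deleted mice, and Cxcr4 at 50.9 ± 39.5 and 84.0 ± 32.4 CPM (SD, n = 6 each). Each was above its own control in 6 of 6 deleted mice. The RNA-binding Samd4 (1.37), Nxpe2 (1.31), the metalloprotease Adam12 (1.29), Spry4, an inhibitor of growth factor signalling (1.24), Fut4 (1.10), Gpihbp1, which carries lipoprotein lipase across capillary endothelium (1.06), the glycoprotein Stc2 (1.01) and the galectin Lgals1 (0.98) also rose, with adjusted p from 0.00310 to 0.0464. Tceal9 (0.76, adjusted p = 3.25e-04) and Marcksl1 (0.57, adjusted p = 6.88e-04) passed in this fit. Tspo (0.71), Ap3s1 (0.66), Ptpre (0.82) and Fam198b (0.90) did so as well, whereas Tln2 (0.89, adjusted p = 0.0544) and Prr18 (0.92, adjusted p = 0.0721) did not.

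With the plate set block Slc16a1, a transporter of lactate and other monocarboxylates, fell in the deleted mice (log2 fold change −1.46, SE 0.20, adjusted p = 6.82e-04), from 55.5 ± 20.7 to 23.7 ± 10.8 CPM (SD, n = 6 each). Phgdh, the first enzyme of serine synthesis (−1.68), Ly75 (−1.65), the kinase Prkcb (−1.58), Cd302 (−1.51), the protease Ctsc (−1.38) and the scaffold protein Iqgap2 (−1.32) fell too, with adjusted p from 6.82e-04 to 0.0176. Mogat2, an acyltransferase of intestinal fat absorption, fell (−1.63, adjusted p = 0.009999). The SD in controls exceeded the mean for Mogat2 (15.5 ± 16.95 CPM) and Ctsc (44.5 ± 45.3 CPM). Kat7 and Tgfbi (−1.21, adjusted p = 2.58e-04) passed in this fit too. Within plate sets the deleted mice also had a lower share of mitochondrially encoded UMIs (mean difference −0.206 percentage points) and of UMIs of the glial list (−0.00793 percentage points), which rests on Glul and Sox9, in 6 of 6 mice each (exact permutation p = 0.0208, the smallest those arrangements give, adjusted p = 0.250 over 32 lists). Transcripts of intestinal epithelium averaged 46.2 ± 71.4 UMIs per 10000 in controls and 26.6 ± 41.3 in deleted mice (exact permutation p = 0.574, n = 6 each). Within plate sets their difference was −21.3 UMIs per 10000, with 2 of 6 deleted mice above their own control (exact permutation p = 0.229). The blocked count was 80 without control 2, 84 without control 3, 79 without control 4, 81 without deleted 1 or deleted 3, 85 without deleted 2 and 316 without deleted 6. DESeq2 with the block called 130 genes.

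Plates LC294 and LC358 carried nearly all of the intestinal UMIs, and the genes were tested again in the other 8 mice, an alternative chosen after seeing the data. Without these plates 13 genes passed (1 higher, 12 lower), and 34 with the plate set block (8 higher, 26 lower). The blocked fit of 8 mice rests on 3 controls, since control 1 is alone in its set, and gave 33 genes without control 1. Of these 34 genes 30 also passed in the blocked fit of 12 mice. Cxcr4 (log2 fold change 1.02, adjusted p = 0.0214), Tceal9 (0.67, adjusted p = 0.0461), Ptpre (1.01, adjusted p = 0.0374) and Igfbp3, which binds insulin-like growth factors (0.75, adjusted p = 0.0407), rose in the blocked fit of 8 mice. Slc1a4 (−1.41, adjusted p = 0.00482), Spock2, a matrix proteoglycan (−1.07, adjusted p = 0.00482), Slc22a8 (−1.38, adjusted p = 0.0107), Tgfbi (−1.24, adjusted p = 0.0107), Nkd1, a feedback inhibitor of Wnt signalling (−1.51, adjusted p = 0.0214), and Slc16a1 (−1.51, adjusted p = 0.0434) fell. Kat7 (−1.88, adjusted p = 0.0642, against −1.96 and 0.0368 with sex as a covariate), Esm1 (1.33, adjusted p = 0.122) and Mogat2 (−1.33, adjusted p = 0.517) did not pass there. Of the 20 named genes of largest change in the blocked fit of 12 mice, Cxcr4 and Slc16a1 alone passed in the 8 mice. The count of 34 was 0 without control 2, control 6 or deleted 1, 4 without control 5, 5 without deleted 4, 85 without deleted 5 and 145 without deleted 6. DESeq2 with the block called 41.

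The wells of 20 cells, sorted from 5 control and 6 deleted mice, gave a separate measurement of the same mice. With the plate set block 56 of 5444 genes passed (17 higher, 39 lower in the deleted mice), 530 had an unadjusted p under 0.05, and DESeq2 called 56. Bsg, a chaperone of monocarboxylate transporters chosen after its values were seen, fell by 1.08 on the log2 scale (SE 0.12, adjusted p = 1.27e-05). Slc22a8 (−2.28), Slc1a4 (−1.84), Nkd1 (−1.64), Slc16a1 (−1.39), the transferrin receptor Tfrc (−1.05) and Spock2 (−0.89) fell, while Cxcr4 (1.66), Tceal9 (1.10), Igfbp3 (0.80) and Marcksl1 (0.69) rose, with adjusted p from 1.15e-04 to 0.0337. Tgfbi had a log2 fold change of −0.38 (adjusted p = 0.862), and Esm1 1.40 (adjusted p = 0.248). Kat7 had 38 UMIs in 16 control wells and 2 UMIs in 18 deleted wells, a ratio of levels of 0.0426 (95% exact counting interval 0.00498 to 0.165), against 0.294 (0.226 to 0.379) between single cells of the mixed plates. Of the 168 genes called in single cells with the block, 88 were tested here, of which 86 (97.7%) had the same direction and 31 passed. These wells come from the same mice and plates, so a difference between mice of any origin recurs in both. In the other 47 arrangements of genotypes within plate sets, a test chosen after seeing the data, the 168 genes of smallest p in single cells shared their direction in a median of 68.9% of those tested (52.2 to 95.6%), and at most 13 passed. These arrangements include ones close to the real split with the genotypes reversed, such as control 1 and deleted 1 to 5 as controls. Without the block the count of 56 became 10, and without plates LC294 and LC358 18. It was 32 without control 2, 24 without control 3, 33 without control 4 or deleted 1, 23 without control 5, 21 without control 6, 28 without deleted 2, 26 without deleted 4 and 86 without deleted 6.

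**Figure D2:**
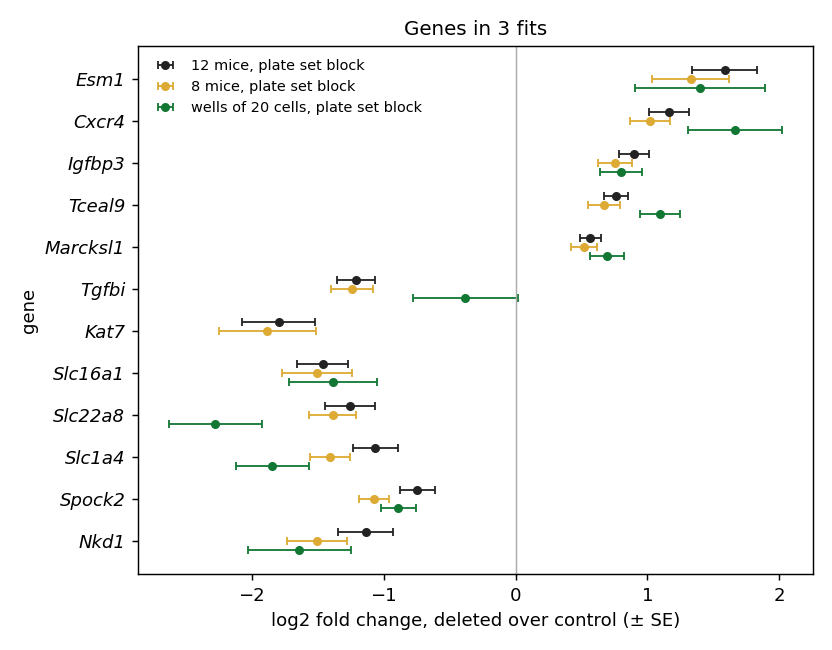
Points give the log2 fold change of deleted over control mice with its SE as a bar, for 12 genes in 3 edgeR fits with the plate set block (black 12 mice, yellow 8 mice, green wells of 20 cells). Each gene lies on 1 side of 0 in every fit that tested it, from 1.66 for Cxcr4 to −2.28 for Slc22a8 in the wells of 20 cells, where Kat7 was not tested.

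With the preset correlation camera called the list of tip genes higher and that of capillary genes lower in the deleted mice, and with an estimated correlation neither. Of 15 tested tip genes 13 had higher values in the planned comparison, where 0 passed by either count, and 15 with the plate set block. In the blocked fit 6 tip genes rose, against 13 adjusted over the list alone. They were Esm1, Cxcr4, Igfbp3 (log2 fold change 0.90, adjusted p = 4.99e-04), the Notch ligand Dll4 (0.57, adjusted p = 0.0129), Mcam (0.52, adjusted p = 0.0232) and Cd34 (0.37, adjusted p = 0.0294). The list was called in the planned fit (camera adjusted p = 3.96e-05) and in the blocked fit (1.29e-23), but not with an estimated correlation (adjusted p = 0.837 and 0.212 with an estimated correlation). Of 12 capillary genes 4 fell with the block, Slc16a1, Slc22a8 (−1.25, adjusted p = 0.00188), Tfrc (−0.59, adjusted p = 0.00312) and Spock2 (−0.74, adjusted p = 0.00753), against 5 lower and 1 higher adjusted over the list alone. In the planned fit 0 capillary genes passed, against 3 lower adjusted over the list alone. The capillary list was called lower in both (camera adjusted p = 4.36e-04 and 5.35e-07; adjusted p = 0.837 and 0.212 with an estimated correlation). Of 19 genes of migration and guidance 17 had higher values in the planned fit, with 0 called and 3 adjusted over the list alone, and 18 with the block. Cxcr4, Marcksl1 and Marcks (0.49, adjusted p = 8.29e-04) rose with the block, against 11 adjusted over the list alone. This list was called higher in both fits (camera adjusted p = 4.18e-09 and 5.47e-17; adjusted p = 0.837 and 0.212 with an estimated correlation). Of 13 arterial genes 0 passed in either fit, against 0 in the planned fit and 3 with the block adjusted over the list alone. The arterial list was called higher in both (camera adjusted p = 0.0173 and 5.45e-04; adjusted p = 0.837 and 0.474 with an estimated correlation). In the arterial list Efnb2 had a log2 fold change of 0.44 (adjusted p = 0.0712) and Hey1 0.79 (adjusted p = 0.0641). By fry, which asks whether the genes of a list move on balance, 0 of the 26 lists passed in either fit (smallest adjusted p = 0.992 and 0.0505). Beside these lists, the shares of UMIs of the mitochondrially encoded list and of the glial list, in effect Glul and Sox9, were each lower in 6 of 6 deleted mice within plate sets (exact permutation p = 0.0208 each). The myeloid share was lower in 5 of 6 (exact permutation p = 0.0625), and none of them passed after adjustment (adjusted p = 0.250 each).

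A further 4 lists were called with the block and not in the planned fit. Of 20 genes of basement membrane and matrix Nid2 (log2 fold change 0.52, adjusted p = 0.00914) and Lamc1 (0.40, adjusted p = 0.0446) rose, and 13 rose and 2 fell adjusted over the list alone (camera adjusted p = 1.32e-06 higher; adjusted p = 0.585 with an estimated correlation). Of 13 Notch genes Dll4 rose, and 2 rose adjusted over the list alone (camera adjusted p = 0.00435; adjusted p = 0.474 with an estimated correlation). Of 13 mitochondrially encoded genes 0 passed and 3 fell adjusted over the list alone (camera adjusted p = 0.0111 lower; adjusted p = 0.212 with an estimated correlation). Of these mt-Co3 had a log2 fold change of −0.19 (adjusted p = 0.103). Of 16 genes of p53 and apoptosis 0 passed by either count (camera adjusted p = 0.0472 higher; adjusted p = 0.726 with an estimated correlation), with Cdkn1a, an inhibitor of cell cycle kinases, at 0.31 (adjusted p = 0.256). In the 8 mice with the block 6 lists were called, with adjusted p from 0.267 to 0.809 with an estimated correlation. Tip genes (2 rose, 9 adjusted over the list alone), migration and guidance (1 and 6) and p53 and apoptosis (0 and 4) were called higher. Capillary genes (3 fell, 6 adjusted over the list alone), Wnt and blood-retina barrier (3 and 3, with 1 higher adjusted over the list alone) and S phase (0 and 0) were called lower. In the wells of 20 cells 8 lists were called, with adjusted p from 0.0608 to 0.348 with an estimated correlation. Tip genes (2 rose, 4 adjusted over the list alone), migration and guidance (2 and 5), basement membrane and matrix (3 and 6) and p53 and apoptosis (1 and 1) were called higher. Capillary (4 fell, 7 adjusted over the list alone), venous (1 and 2), ribosomal (1 and 1) and mitochondrially encoded genes (0 and 6) were called lower. By fry 5 lists passed in those wells (capillary, venous, migration and guidance, ribosomal, p53 and apoptosis) and 0 in the 8 mice. Cdkn1a rose in the wells of 20 cells (0.66, adjusted p = 0.0149).

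Lists of the cell cycle and of the complexes of HBO1 were not called in the 12 mice, with or without the block. S phase was called lower in the 8 mice with the block (camera adjusted p = 0.0151; adjusted p = 0.809 with an estimated correlation). In the blocked fit of 12 mice 0 genes passed among 15 proliferating genes (camera adjusted p = 0.893), 16 of replication licensing (0.577), 20 of S phase (0.0655) and 25 of G2/M phase (0.986), and 0 adjusted over each list alone. The replication factors Cdt1 (log2 fold change −0.39, adjusted p = 0.458) and Mcm2 (−0.34, adjusted p = 0.584) and the proliferation marker Mki67 (−0.12, adjusted p = 0.818) did not pass. Among 13 genes of the HBO1 and MYST complexes Kat7 alone fell, by either count (camera adjusted p = 0.577), and its partners Meaf6 (−0.40, adjusted p = 0.615), Brd1 (0.14, adjusted p = 0.768) and Jade1 (−0.21, adjusted p = 0.773) did not pass. Of 23 genes of Wnt signalling and the blood-retina barrier Plvap, a protein of endothelial fenestrae, rose (0.57, adjusted p = 0.0104) and Slc16a1, Spock2 and Nkd1 (−1.13, adjusted p = 0.00786) fell, against 4 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.508). Of 10 venous genes Slc38a5, an amino acid transporter, and the apelin receptor Aplnr fell (−0.81 and −0.49, adjusted p = 0.0106 and 0.0467), against 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.844). Of 15 pan-endothelial genes Emcn, a surface glycoprotein of veins and capillaries, rose (0.50, adjusted p = 0.0145), against 4 adjusted over the list alone (camera adjusted p = 0.0508). Cdh5, the cadherin of endothelial junctions, did not pass (0.32, adjusted p = 0.0990). In the planned fit 0 members of these lists passed, against 1 higher and 3 lower of Wnt and the blood-retina barrier, 1 higher of the venous list and 1 lower of the HBO1 and MYST complexes adjusted over the list alone.

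In the remaining lists camera gave an adjusted p of 0.297 for VEGF and angiopoietin signalling, 0.759 for BMP and TGF-beta signalling, 0.126 for hypoxia, 0.986 for glycolysis, 0.101 for oxidative phosphorylation, 0.508 for ribosomal proteins, 0.577 for the interferon response, 0.759 for immediate early genes, 0.577 for cholesterol synthesis and 0.101 for leukocyte adhesion with the block. Genes of the interferon response passed in both directions, 2 higher and 3 lower by either count. In the other 9 lists 0 passed, against 1 higher for hypoxia, 1 for glycolysis, 2 for leukocyte adhesion and 0 for the rest adjusted over the list alone. Angpt2, the angiopoietin released by sprouting endothelium, had a log2 fold change of 0.63 (adjusted p = 0.193), and the glycolytic enzyme Pkm 0.27 (adjusted p = 0.0650). The sign of the test differed from that of the median or mean with the block for the HBO1 and MYST complexes (median 0.07, mean −0.13, test lower), G2/M phase (0.01 and 0.01, lower) and immediate early genes (−0.02 and 0.02, higher). In the planned fit it differed for those lists and for the pan-endothelial, replication licensing, Wnt, BMP and ribosomal lists, all with medians between −0.03 and 0.01. The planned count of 4 lists became 9 without control 1 and 10 without deleted 3.

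As shares of all UMIs, none of the 32 lists differed between the genotypes after adjustment (smallest adjusted p = 0.996 by exact permutation over mice, and 0.250 within plate sets). Tip genes took 0.190 ± 0.0868% of UMIs in 6 control mice and 0.238 ± 0.0672% in 6 deleted mice (exact permutation p = 0.310). Within plate sets the tip share was higher in 6 of 6 deleted mice, by 0.0648 percentage points (exact permutation p = 0.0417). Migration and guidance genes took 0.379 ± 0.105% and 0.473 ± 0.0944% (n = 6 each, exact permutation p = 0.139), and within plate sets the share was higher in 6 of 6 deleted mice (exact permutation p = 0.0417). Capillary genes took 0.374 ± 0.125% and 0.315 ± 0.0726% (n = 6 each, exact permutation p = 0.320, within plate sets 0.0833). Proliferating genes took 0.0947 ± 0.0355% and 0.0914 ± 0.0211% (n = 6 each, exact permutation p = 0.848). Markers of other retinal cells were scarce, with 0.00485 and 0.00721% of UMIs in control and deleted mice for mural cells (exact permutation p = 0.333), 0.00649 and 0.00520% for myeloid cells (0.368), 3.26e-04 and 2.84e-04% for photoreceptors (0.924), 0.0350 and 0.0280% for the glial list (0.297), 0.00279 and 0.00286% for neurons (0.890) and 0.00304 and 0.00195% for blood (0.805, n = 6 mice per genotype). The glial list is no measure of glia here, since it rested on Glul (252 ± 67.1 CPM in controls and 218 ± 63.95 CPM in deleted mice), which was raised in the capillary-like and arterial-like clusters, and on Sox9 (93.6 ± 136 and 58.8 ± 83.1 CPM, n = 6 each). Sox9 stood at 142 to 313 CPM in the 4 mice of plates LC294 and LC358 and at most at 14.4 CPM in the others. Of the lists of intestinal epithelium, enterocyte genes took 10.4 ± 20.3 and 2.25 ± 4.37 UMIs per 10000, goblet genes 1.40 ± 2.19 and 2.53 ± 5.87, tuft genes 13.1 ± 20.8 and 7.61 ± 12.4, and genes of epithelium in general 21.3 ± 32.7 and 14.2 ± 21.99 (n = 6 each, smallest exact permutation p = 0.472, adjusted 0.717).

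Clustering gave 13 clusters, of which 1 and 3 were capillary-like, 4 and 8 proliferating-like, 6 tip-like, 7 arterial-like and 13 mural-like (6 cells). Clusters 2, 5 and 10 stayed unnamed. Cluster 2 was led by genes of DNA replication such as Cdt1 and Mcm3 together with Olfm4 and Cps1, which are expressed in intestinal epithelium, and held 26.1% of its cells on plates LC294 and LC358. Cluster 5, with a median of 4102 UMIs per cell, was led by defensin genes of intestinal Paneth cells and held 20.9% of its cells on those plates. All 609 defensin UMIs of cluster 5 came from those plates and lay in 15 of its 239 cells, and plates LC280, LC392, LC396 and LC398 had 0 defensin UMIs in all. Cluster 10 (74 cells) was led by small RNAs such as Rn7sk, with 67.6% of its cells on plates LC294 and LC358. Clusters 9, 11 and 12 were led by genes of intestinal tuft cells, enterocytes and goblet cells, with 99.1%, 100% and 100% of their cells on plates LC294 and LC358. Unnamed clusters held 35.6 ± 20.8% of cells in control mice and 38.5 ± 16.3% in deleted mice (SD, n = 6 each). Clusters 1, 3, 6 and 7 were led partly by genes that differ by genotype and were not compared. None of the others differed in share (smallest adjusted p = 0.864, exact permutation), and proliferating-like cells made up 18.1 ± 4.61% of cells in controls and 17.6 ± 5.37% in deleted mice (n = 6 each, exact permutation p = 0.877). This class pools clusters 4 and 8, which differed by −2.78 and 2.25 percentage points, deleted minus control (exact permutation p = 0.160 and 0.203). Cluster 2, led by genes of DNA replication, held 11.8 ± 2.58% and 14.4 ± 4.97% of cells (n = 6 each, exact permutation p = 0.294). When 1720 genes that differed by genotype at an unadjusted p under 0.05 were left out of the clustering, an alternative chosen after seeing the data, tip-like cells made up 1.42 ± 1.79% of cells in control mice and 4.48 ± 4.05% in deleted mice (n = 6 each, exact permutation p = 0.0758). The genes left out still counted in naming the clusters. Of 16 tip genes 15 named this tip-like cluster, among them Esm1, Cxcr4, Igfbp3, Dll4, Mcam and Cd34, which rose in the blocked fit. Within plate sets the tip-like share was higher in 6 of 6 deleted mice, by 3.77 percentage points (exact permutation p = 0.0417). The mean difference was 1.44 percentage points without deleted 1, against 3.06 with all mice. The difference in the tip-like share of cells, clustered without genes differing by genotype, passed the exact permutation test without control 1 (3.59), deleted 2 (3.51) or deleted 6 (3.63).

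**Figure D3:**
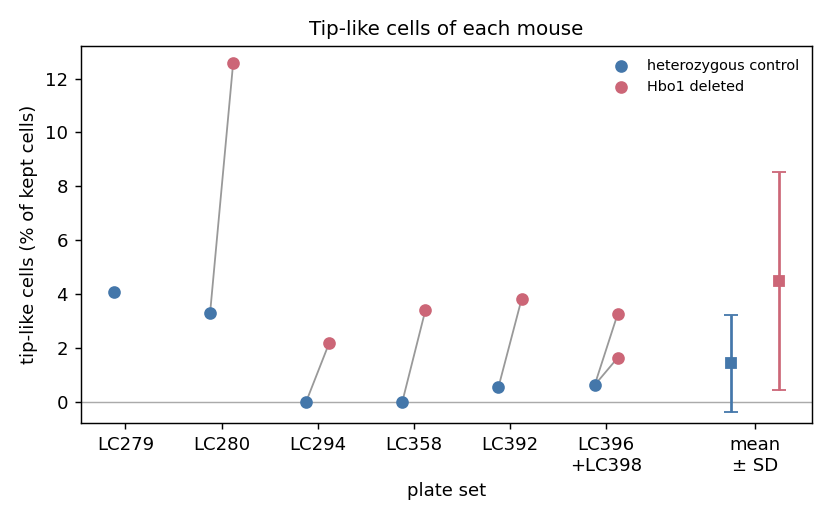
Each point is the share of tip-like cells among the kept cells of 1 mouse in percent, clustered without genes that differ by genotype, controls in blue and deleted mice in red, by plate set, with lines joining the mice of a set and squares giving the mean ± SD of 6 mice. Each of the 6 deleted mice lies above the control of its set, and deleted 1 stands highest at 12.6%.

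Within capillary-like cells Slc16a1 fell (log2 fold change −1.94, SE 0.31, adjusted p = 0.0195), and Marcksl1 (0.82, SE 0.15, adjusted p = 0.0305) and the membrane protein Emp1 (0.99, SE 0.17, adjusted p = 0.0305) rose in the deleted mice, with n = 6 mice per genotype. The class pools clusters 1 and 3, which held 17.0 ± 8.28% and 17.3 ± 7.49% of cells in controls and 13.6 ± 2.86% and 8.89 ± 4.73% in deleted mice (SD, n = 6 each). These shares are given as the makeup of the class, which was not held equal between the genotypes, and not as a comparison, since genes that differ by genotype lead the clusters. No other gene passed, and 306 had an unadjusted p under 0.05. The plate set block raised the count to 33 (7 higher, 26 lower). The count of 3 became 1 without control 2 or control 5, 0 without control 3, control 6, deleted 1, deleted 3 or deleted 6, 8 without control 4 and 5 without deleted 5. Within arterial-like cells (4 control and 5 deleted mice) edgeR called 0 genes, with 188 at an unadjusted p under 0.05, against 2 with the plate set block and 145 with no filter on low counts. It called 2 without control 6 and 1 without deleted 1 or deleted 3. Within proliferating-like cells edgeR called 0 genes (295 at an unadjusted p under 0.05, n = 6 mice per genotype) and 4 with the plate set block. Capillary genes were called lower within capillary-like, arterial-like and proliferating-like cells (camera adjusted p = 3.32e-05, 1.96e-06 and 0.0116; adjusted p = 0.342, 0.486 and 0.814 with an estimated correlation). Of them 1, 0 and 0 fell, against 3, 3 and 1 adjusted over the list alone. In all, camera called 4, 8 and 3 lists in these classes. Without deleted 1 it called 0 lists in proliferating-like cells. In arterial-like cells it called 2 with the plate set block, 2 without deleted 3 and 2 without plates LC294 and LC358. None of the 4 control mice with enough arterial-like cells came from those plates, whereas deleted 2 and deleted 3 did. Genotype can therefore not be told apart from the intestinal transcripts of those plates in the arterial-like fit without the block. Tip-like cells were not tested, since only 2 control mice held 10 of them.

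The genotype effect itself was compared between classes. It differed between arterial-like and proliferating-like cells for 2 genes, Cdkn1c, a cell cycle inhibitor (difference of log2 fold changes 3.13, proliferating-like minus arterial-like, edgeR adjusted p = 0.0110), and Malat1, a nuclear non-coding RNA (330 at an unadjusted p under 0.05). Cdkn1c averaged 77.9 CPM over all 12 mice and 12.1 CPM over the 8 mice without plates LC294 and LC358. Of the mice with enough arterial-like cells, deleted 2 and deleted 3 came from those plates and none of the controls did. In comparisons with arterial-like cells, genotype can therefore not be told apart from the intestinal transcripts of those plates. The effect differed for 0 genes in edgeR between capillary-like and arterial-like cells (282 at an unadjusted p under 0.05) and for 0 between capillary-like and proliferating-like cells (350), where Plvap had the smallest p (0.86, adjusted p = 0.645).

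The classes themselves were described within each genotype, with the mouse as a block. In control mice 828 genes were higher and 1014 lower in capillary-like cells than in the other cells, against 408 and 515 in arterial-like and 621 and 664 in proliferating-like cells. In deleted mice the counts were 478 and 578 for capillary-like, 402 and 474 for arterial-like, 772 and 767 for proliferating-like and 321 and 275 for tip-like cells. These genes define the clusters and are not findings.

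The amount of RNA per cell did not differ detectably between the genotypes. The median cell held 11991 ± 3358 UMIs in control mice and 12083 ± 3447 in deleted mice (SD, n = 6 each, exact permutation p = 0.976). Thinned to 1000 UMIs, it held 713 ± 32.0 and 716 ± 30.8 genes (n = 6 each, exact permutation p = 0.844), and unthinned 3656 ± 499 and 3652 ± 680 genes. Endogenous UMIs per ERCC UMI were 14.6 ± 6.15 and 13.4 ± 7.61 (n = 6 each, exact permutation p = 0.703). The median mitochondrially encoded share of a cell was 7.47 ± 3.36% in controls and 7.20 ± 3.54% in deleted mice (n = 6 each, exact permutation p = 0.781).

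The sorted cells of deleted mice had higher EGFP values within plate sets, without passing after adjustment. The median EGFP intensity was 43818 ± 8071 in control mice and 51606 ± 7725 in deleted mice (SD, n = 6 each, exact permutation p = 0.121), and within plate sets it was higher in 6 of 6 deleted mice by 9679 (exact permutation p = 0.0208, the smallest possible, adjusted p = 0.0521 over 5 channels). Forward scatter was higher in 6 of 6 deleted mice by 16689 (exact permutation p = 0.0208, adjusted p = 0.0521) and side scatter in 6 of 6 by 14395 (exact permutation p = 0.0833, adjusted p = 0.139). The tdTomato and PE-Cy7 channels were higher in 4 of 6 deleted mice each, with mean differences of −455 and 8616 (exact permutation within plate sets, p = 0.667 and 0.250). None of the channels passed after adjustment.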

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

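The tests of explanations in this part were chosen only after the results they bear on had been seen, as were the comparisons of sort intensities, of intestinal and sex-linked UMIs and of the wells of 20 cells. In 48 groups of 6 mice the highest and lowest values were compared with the rest by Dixon's test, which by chance alone picks about 1 in 20 groups. Control 1 stood apart in the share of UMIs from genes of p53 and apoptosis, 0.119% against 0.0751 to 0.0916% in the other controls. Control 4 had a median of 18535 UMIs per cell against 8726 to 11447. Deleted 1 had 28.0 endogenous UMIs per ERCC UMI against 8.03 to 14.4 in the other deleted mice, and 12.6% tip-like cells against 1.63 to 3.80%. The effect of genotype differed between arterial-like and proliferating-like cells for 2 genes by the interaction test. Plates LC294 and LC358 entered that test through deleted mice alone. Outside the main measurement, EGFP intensity was higher within plate sets by 9679 and forward scatter by 16689, and the wells of 20 cells gave 56 genes.

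Intestinal transcripts appeared on plates LC294 and LC358, at 97.9 and 121 of 10000 UMIs, against 0.114 to 1.41 on the other plates; Krt18 reached 1616 CPM and Apoa1 406 CPM on these plates, against at most 18.7 CPM for any gene of the 4 lists on plate LC279 (Krt8) and 7.92 CPM on the other 4 plates (Lgals4). On plate LC279, which holds control 1 alone, 64.6% of cells had an intestinal UMI. The sort on PECAM1 and EGFP would remove such cells, and the lists were written after the clusters had been seen. Free RNA of 1 source would keep goblet and enterocyte UMIs in 1 ratio, whereas their chi-square per degree of freedom was 46.5 over 272 wells of plate LC358. Intestinal cells sorted in place of endothelial cells would lack endothelial UMIs, whereas 99.3% of 293 wells with at least 20 intestinal UMIs held at least 5 pan-endothelial UMIs. Those 293 wells are nearly all 294 kept cells of plate LC358, and 5 is low against that plate's median of 72 pan-endothelial UMIs. The test therefore counts against such cells in every well and cannot exclude them in some. Reads of other libraries with the same barcodes remain a candidate source, since the median number of intestinal UMIs in wells of 20 cells of those plates was at most 0.833 times that in wells of 1 cell. No biological explanation was tested, and other libraries were not analysed here.

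UMIs of the other sex appeared where a plate held both sexes: Xist, expressed from the inactive X chromosome of females, stood at 110 CPM in male wells of plate LC392, 115 CPM in those of plate LC396 and 35.1 CPM in those of plate LC294. Of 204 male wells with an Xist UMI on plates LC392 and LC396 78.9%, and of 47 on plate LC294 72.3%, also held a Y-linked UMI. Wells holding a cell of the other mouse in place of their own would tend to lack Y-linked UMIs. Female wells held them too, however, with 146 over 184 wells of plate LC392, 75 over 184 of plate LC396 and 136 over 183 of plate LC294. The test therefore cannot exclude misplaced cells as a part of the source. Exchange of UMIs between wells of a plate may be the source, as Xist in male wells of the plates of males alone was 0.00929 times the level of plates LC392 and LC396 and 0.0295 times that of plate LC294. Such exchange may also make fold changes between mice that share a plate smaller in single cells, for other genes as for Kat7, which was not tested. No biological explanation was tested.

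Kat7 UMIs remained in the single cells of all 6 deleted mice, 7 to 23 per mouse. Cells that escaped deletion as the whole source would give the same ratio in wells of 20 cells, where the ratio of deleted to control was instead 0.145 times that in single cells, with an upper 95% limit of 0.584. Other-sex UMIs do not decide whether exchange between wells is the whole source. The Kat7 ratio exceeded the larger ratio of other-sex UMIs by at most 0.0830, which on plate LC392 (0.409, counting interval 0.228 to 0.711, against 0.326) lies within counting error, and on plate LC294 it lay below (0.198 against 0.399). A low true level, such as a transcript left by the deleted copies, would as the whole source also give the same ratio in both kinds of wells. The ratio was 0.0426 (0.00498 to 0.165) in wells of 20 cells and 0.294 (0.226 to 0.379) in single cells of the mixed plates, which argues against it as the whole source. These intervals cover counting error, and the lower ratio rests on 2 UMIs in deleted wells. A smaller part from such a transcript or from escaped cells, beside exchange, stays open and untested.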

How the results depend on the processing

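The plate set block, DESeq2, other gene and cell filters, thinning and leaving out mice or plates were planned; the blocked fits as results of their own, the 8 mice, leaving out the clusters led by intestinal genes, sex as a covariate, clustering without genes that differ by genotype, the wells of 20 cells and permutations within plate sets were chosen after seeing the data. Of 685 blocked values of 34 named genes under the alternatives, 583 kept their direction and their side of the threshold, 94 lost and 8 gained the call, and 0 reversed. After adjustment 0 shares of UMIs per list and of clusters passed under each alternative; unadjusted, the shares of UMIs of tip (0.0648), migration and guidance (0.0877), mitochondrially encoded (−0.206) and glial list genes (−0.00793) passed within plate sets, as did the capillary list, share of UMIs (−0.0946), and the migration and guidance list, share of UMIs (0.0867), in the 8 mice. Except where stated, the cause of a change was not tested. The count of 1 gene became 0 with no filter on low counts, 0 with cells thinned to 1000 UMIs (3443 genes tested), 2 without the mural-like and intestinal clusters, 39 with DESeq2, 168 with the plate set block, 0 without plate LC280, LC358, LC396 or LC398, 2 without plate LC392, 323 with sums per plate and genotype, 13 without plates LC294 and LC358 and 34 with the block as well; without each mouse it ranged from 0 to 4. The sums per plate and genotype counted control 6 once on each of plates LC396 and LC398 and left out control 1. The p-values of that fit cover the spread between plates and not mice. The blocked count of 168 became 571 with no filter, 19 thinned and 109 without the mural-like and intestinal clusters, and 79 to 316 without each mouse. The blocked count of 34 in 8 mice became 155 with no filter, 6 thinned and 0 to 145 without each mouse. The count of 56 in wells of 20 cells became 10 without the block, 89 with no filter, 18 without plates LC294 and LC358 and 21 to 86 without each mouse. With sex as a covariate the counts were 1 without the block, 131 with it and 38 in the 8 mice with it. In capillary-like cells 3 became 33 with the block, 5 in the 8 mice, 16 there with the block and 0 to 8 without each mouse. In arterial-like cells 0 became 145 with no filter, 2 with the block, 5 without plates LC294 and LC358, 1 there with the block and 0 to 2 without each mouse. In proliferating-like cells 0 became 4 with the block, 2 in the 8 mice, with or without the block, and 0 without each mouse. The 4 lists became 2 thinned, 8 with the block, 9 with the mixed plates, without plate LC279 or with sums per plate and genotype, and 3 to 10 without each mouse. Kat7 passed with DESeq2 (−1.65), the block (−1.80) and sums per plate and genotype (−1.85), ranged from −1.89 to −1.51 without each mouse and has no value thinned, where the filter removed it. The difference in endogenous RNA per cell, UMIs of the median cell, reversed on the mixed plates (−560.45) and within plate sets (−120), and ranged from −771 to 1401 without each mouse. Genes at 1000 UMIs ranged from −6.98 to 13.9 and UMIs per ERCC UMI from −4.18 to 1.03. The difference in proliferating-like cells reversed in the 8 mice (0.310) and ranged from −1.94 to 1.10, and that in the proliferating list reversed as a mean of each cell's share (5.2e-04) and ranged from −0.0115 to 0.00780. Tip-like cells passed on the mixed plates (3.59) and within plate sets (3.77), and ranged from 1.44 to 3.63. Depth limits what could be seen: Kat7 rested on 7 to 56 UMIs per mouse, so small changes in genes of that level were not detectable.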

Other observations

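The tests of hypotheses in this part were chosen after the results had been seen, as were the blocked fits as results of their own, the 8 mice, the wells of 20 cells and the genes named in the next paragraphs. Single genes that fell in the blocked fit, picked by eye among those called, were Slc16a9 (log2 fold change −1.15, SE 0.20, edgeR adjusted p = 0.00471), the taurine transporter Slc6a6 (−0.80, SE 0.14, adjusted p = 0.00616) and the thyroxine transporter Slco1c1 (−0.81, SE 0.13, adjusted p = 0.00267). In the wells of 20 cells Slc6a6 (−1.07, adjusted p = 0.00145) and Slco1c1 (−1.33, adjusted p = 0.0313) fell as well, as they did in the 8 mice with the block (−1.03, adjusted p = 0.0392, and −0.83, adjusted p = 0.0407). Bsg, the chaperone of monocarboxylate transporters, fell in the blocked fit of 12 mice (−0.52, adjusted p = 0.00293) and of 8 mice (−0.60, adjusted p = 0.0434). No group of transporters was tested, and the picked genes do not stand for one.

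Among genes of the interferon response list in the blocked fit, the class I histocompatibility genes H2-K1 (log2 fold change −0.88, SE 0.13, edgeR adjusted p = 0.00107) and H2-D1 (−0.40, SE 0.09, adjusted p = 0.0196) and the interferon-induced Ifi27 (−0.90, SE 0.17, adjusted p = 0.0106) fell, and Ifitm3 (0.47, SE 0.10, adjusted p = 0.0167) and Bst2 (0.51, SE 0.12, adjusted p = 0.0461), 2 interferon-induced membrane proteins, rose. H2-K1 belongs to a family of near-identical genes, and how the counting divided shared reads is not given in the sources used here. Outside that list Vim, the intermediate filament vimentin (0.63, SE 0.07, adjusted p = 2.05e-04), Emp1 (0.93, SE 0.11, adjusted p = 2.58e-04) and the cadherin Cdh13 (0.79, SE 0.11, adjusted p = 6.82e-04) rose, and in the wells of 20 cells Vim (0.48, adjusted p = 0.0321), Emp1 (1.03, adjusted p = 0.0199) and Cdh13 (1.17, adjusted p = 9.10e-04) rose as well.

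Other splits of the mice were tested for each count of genes. In the blocked fit 1 of the 48 arrangements within plate sets, the real one, gave as many as 168 genes, and the highest other gave 86. That other took control 1 and deleted 1 to 5 as controls, which is close to the real split with the genotypes reversed. A share of 0.0208 is the smallest these arrangements give. This fit was described as a result of its own after the data were seen, so the share counts against chance without excluding it. In the wells of 20 cells 1 of 48 gave as many as 56, and the highest other, with deleted 1 to 5 as controls, gave 23. These wells come from the same mice and plates, so this is no separate evidence against chance. Without the block 7 of 100 splits gave at least the real 1 gene, so chance is not excluded, and the highest gave 527 when control 1, control 3, control 4, control 6, deleted 2 and deleted 3 formed a group. That split keeps both mice of plates LC294 and LC358 together and points to a structure of the samples, and the blocked count of 168 is the value within plate sets. In the 8 mice without the block 3 of 35 splits gave at least the real 13 genes, so chance is not excluded, and the highest other, 670, also points to a structure. With the block the 8 mice allow 12 splits, too few for a share under 0.05, with 34 genes in the real split, 1 split as large and 0 genes in the highest other. In capillary-like cells 6 of 100 splits gave at least the real 3 genes, with 76 in the highest other, so chance is not excluded. In arterial-like and proliferating-like cells the real count was 0, which 100 of 100 splits reach by construction, so the splits decide nothing there, and the highest others were 23 and 81. Splits with 23, 76 and 81 genes point to a structure of the samples.

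Other splits were also tested for each count of lists. In the planned fit 78 of 100 splits called at least the real 4 lists, with 17 in the highest other, and with the plate set block 23 of 48 called at least the real 8, with 17 in the highest other, so chance is not excluded for either count. In the wells of 20 cells 3 of 48 called at least the real 8, with 9 in the highest other, and chance is not excluded at a share of 0.05. In the 8 mice with the block 9 of 12 splits called at least the real 6, with 13 in the highest other, and 12 splits are too few for a share under 0.05.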
